A study of Mus musculus with 6 samples.

How the data were processed

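Messenger RNA was measured in 6 mice with 1 Affymetrix mouse genome array each, 3 noise-exposed and 3 unexposed; groups and replicate numbers were taken from the labels, which describe separate animals. Per the labels' protocols, modioli of both ears were pooled, the RNA of a mouse was reverse transcribed, linearly amplified and biotinylated, and the total RNA input ranged from 8 to 21 ng and the amplified cDNA from 5.2 to 6.4 µg. Amplification of such small inputs can widen the spread between arrays, and a probe set reports the part of a transcript that its probes cover. Control probe sets at the end of the beta-actin transcript exceeded those at its start by 2.23, 2.04 and 2.28 (log2) on the noise-exposed arrays. On the unexposed arrays the excess was 1.93, 1.97 and 2.08. For Gapdh it was 1.32, 1.17 and 1.48 against 1.23, 1.21 and 1.32. The groups overlapped in both, and a role of RNA quality was not tested.

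The authors deposited log2 signals, 1 value per probe set. Per their deposited code file these were made by robust multi-array averaging (RMA: background correction, quantile normalization and a median-polish summary of all 6 arrays together) in R 2.6.1 with Bioconductor release 2.1. Quantile normalization gives every array nearly the same distribution, so a change of most transcripts in 1 direction would not be visible. The authors' deposited receptor table holds the same log2 values for 1369 probe sets selected by Gene Ontology terms and symbols, and it differed from the value table by at most 5e-06. Their deposited list of called receptors gives a score, a fold ratio and a q-value in percent per probe set; per its header it was made with significance analysis of microarrays (SAM, version 3.02) with a rank statistic, 5000 permutations and a minimum fold change of 1.45. A further table deposited by the authors gives the mean log2 signal over 17 arrays, normalized together, and a Bonferroni-corrected p-value of a one-sided test against 5.1; 11 of those arrays belong to other series and are not analysed here.

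Of 45101 probe sets, 34958 had 1 gene symbol in the annotation table, 932 had several and 9211 had none and are unnamed here; 34754 were matched to the RefSeq gene table by their Entrez ID. No genes were named from probe sets with several symbols, and Ddx3y of the sex-linked list was not analysed here. No coordinates are given, since the array files name no genome build. The 64 control probe sets were left out of the tests. A probe set was tested if it lay above the authors' cutoff of 4.25 on at least 3 of the 6 arrays, which left 25200 probe sets. For genes and gene lists, 1 probe set per gene was used, the one with the highest mean over the 6 arrays, which gave 11861 genes; of 58 named genes with several tested probe sets, 25 had probe sets of opposite sign.

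Noise-exposed and unexposed arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05); a log2 fold change is noise-exposed minus unexposed. The receptor probe sets above the cutoff on all 6 arrays were compared with an own implementation of SAM with a t-type score, all 20 assignments of the arrays and q under 0.05. This score was fixed before the data were examined and differs from the rank statistic of the authors' list. Its q uses the median number of false calls over the assignments. A single extreme probe set can therefore get a q of 0, which gives no error rate with so few arrays. In addition, probe sets were counted whose groups did not overlap and whose ratio passed the authors' minimum fold change. This rank criterion does not recompute the authors' score or q-value. The 33 fixed gene lists other than the sex-linked genes were tested where at least 3 genes were measured, with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1.

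Lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from those named below as chosen later. The rule took the lowest unadjusted p per direction (6 genes each where none is called), every measured Wnt receptor, up to 4 genes of every other list by unadjusted p, the sex-linked genes, the 5 highest and 5 lowest SAM scores and the gene in the title; genes of the authors' list, detected receptors given as examples, and Epha3 among the separated probe sets were added after their values were seen. Alternatives covered normalization, signal filter, covariates, the replicate number as a block, subsets by sex and day, and each array left out.

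The statistics were tested on simulated data with the means and spread of these arrays, each probe set drawn independently. For the comparison over 25200 probe sets limma called 34 of 100 probe sets changed by 1 on the log2 scale, 85 of 100 changed by 2, and 8 unchanged ones. These 200 were changed together, in both directions, and many true changes loosen the adjusted threshold. The shares therefore do not give the power for an isolated change. For the 473 receptor probe sets SAM called 85% of 40 raised by 1, with 5 unchanged ones, and 100% of 40 raised by 2, with 1 unchanged one. All 40 were raised together and none was lowered. For the gene lists, camera found a list lowered by 0.5 and called 0 other lists. The simulated genes were uncorrelated, whereas the estimated correlation reached 0.81 in the central glia list. The simulation therefore gives no error rate of camera for lists of correlated genes.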

Results

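The modiolus is the bony core of the cochlea and holds the spiral ganglion, whose neurons carry signals from the hair cells to the brain, together with their glia, vessels and bone. Messenger RNA was measured in modioli of 6 CBA/CaJ mice with Affymetrix mouse genome arrays, 1 array per mouse, with both ears of a mouse pooled. In the noise-exposed group, 3 mice had been exposed at 4 weeks of age for 5 h to noise between 5 and 20 kHz at 110 dB SPL. The unexposed group held 3 mice kept in the holding room. All mice were killed at about 8 weeks of age, so the comparison describes the tissue weeks after the exposure. Between 24671 and 25371 probe sets per array lay above the authors' signal cutoff of 4.25 on the log2 scale, and the number of arrays limits the precision. Pearson's r across probe sets was 0.988 to 0.991 within the noise-exposed group, 0.975 to 0.985 within the unexposed group and 0.979 to 0.988 between the groups; probe sets are not independent replicates. The noise-exposed mice were 3 females of 1 litter, dissected on the first of 2 days. The unexposed mice were 1 female and 2 males of 3 other litters, and 1 of them, unexposed replicate 1, was dissected on the first day.

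The study asked which guidance receptors of neurons were present in the adult cochlea. Of the Wnt receptors, 11 of the 16 genes in the fixed list had a probe set above the cutoff on all 6 arrays. These were the Frizzled receptors Fzd1, Fzd2, Fzd3, Fzd4, Fzd5, Fzd6, Fzd7 and Fzd9, the Frizzled co-receptor Lrp6, and the receptor tyrosine kinases Ryk and Ror1, which bind Wnt proteins. Fzd8, Fzd10, Lrp5, Ror2 and Ptk7 had no probe set above it on all 6 arrays. The brightest probe set of Lrp6 averaged 10.62 ± 0.25 (SD, n = 6) on the log2 scale, that of Fzd7 9.83 ± 0.25 and that of Fzd2 9.78 ± 0.15. Fzd9, which the study's title names, averaged 5.12 ± 0.36 over the 6 arrays and lay above the cutoff on each of them. Levels of different probe sets depend on the probes as well as on the transcript, so they give no ranking of the genes.

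Receptors of the other guidance and growth factor families were detected at different shares. Of the receptors for netrins, slits, semaphorins and hedgehog proteins, which steer growing axons, 17 of 25 genes on the array passed, among them Neo1, Plxnb1 and Cdon. Of the Eph receptors and ephrins, which act in contact repulsion between cells, 13 of 21 passed, with Epha4 at 10.75 ± 0.21 (SD, n = 3) in unexposed mice. Of the receptors for myelin inhibitors and the related phosphatases, 7 of 9 passed, with Ptprs at 12.2 ± 0.04 in the same mice. Of the neurotrophic and growth factor receptors, 29 of 31 passed, and Gfra3 and Erbb4 did not. Over the 5 receptor lists together, 76 of 101 genes on the array passed on all 6 arrays and 81 on at least 3. In the authors' deposited table of 17 arrays, 11 of them from other series, Fzd9 had a mean of 6.95 and a corrected p of 9.7e-07 for lying above a cutoff of 5.1. Among the same deposited values, 7 of 13 Wnt receptor genes, 13 of 25 genes of the ephrin group, 13 of 15 of the semaphorin group and 3 of 5 of the netrin group had a probe set with a corrected p under 0.05. Fzd5 (mean 5.69, corrected p of 0.693) and Ror1 (mean 5.19) did not pass there on the probe sets used here. Fzd3, Fzd4 and Lrp6 did not pass on the probe sets held there, which lack the brightest ones used here. That cutoff of 5.1 is also higher than the 4.25 used for the 6 arrays. Fzd10 passed in the authors' deposited table, with a mean of 6.45 and a corrected p of 7.4e-06, and lay below the cutoff on each of the 6 arrays of the present series.

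**Figure D1:**
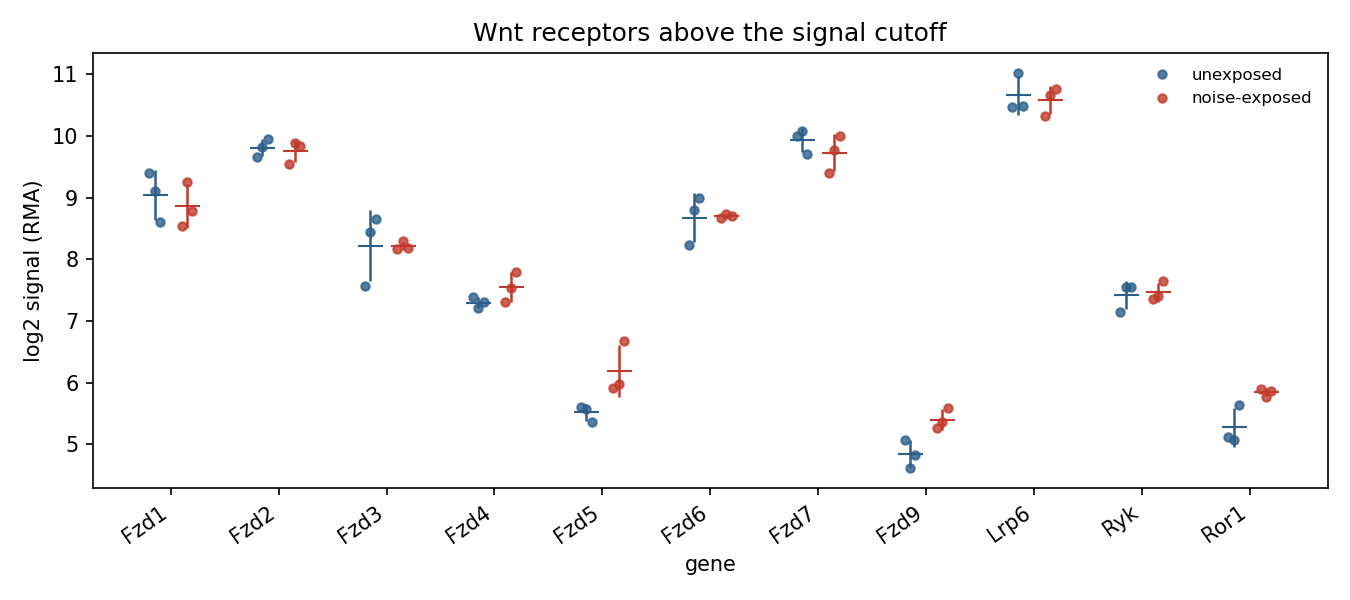
Log2 signal of the 11 detected Wnt receptors (y axis) by gene (x axis) in unexposed (blue) and noise-exposed (red) mice; points are single arrays, horizontal dashes are means and vertical lines are SD (n = 3). Fzd9, Fzd5 and Ror1 show no overlap between the groups, with log2 fold changes of 0.56, 0.67 and 0.57, and none of the 11 passed the adjusted threshold.

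The next question was whether Wnt receptors differed between noise-exposed and unexposed modioli. Fzd9 averaged 5.40 ± 0.17 (SD, n = 3) in noise-exposed and 4.84 ± 0.23 in unexposed mice, a log2 fold change of 0.56 (SE 0.17, 95% interval 0.16 to 0.96). Fzd5 averaged 6.19 ± 0.42 against 5.52 ± 0.14, a log2 fold change of 0.67 (SE 0.22). Ror1 averaged 5.85 ± 0.07 against 5.28 ± 0.32, a log2 fold change of 0.57 (SE 0.19). Each of the 3 was higher in all 3 noise-exposed than in all 3 unexposed mice, and none passed the test (limma, adjusted p = 0.667 for each over all probe sets). Adjusted over the list alone, 0 of the 11 measured Wnt receptors passed, with a lowest adjusted p of 0.0653, and 0 passed over all genes tested. The other 8 had log2 fold changes between -0.20 (Fzd7) and 0.25 (Fzd4). The list as a group had a median log2 fold change of 0.03 and a camera adjusted p of 0.688; after renewed quantile normalization the median was -0.02. With the day of dissection in the model the log2 fold change of Fzd9 was 0.33 (adjusted p = 0.838), and with sex in the model 0.78 (adjusted p = 0.380). Over the alternatives run it lay between these values, which rest on unexposed replicate 1 alone and unexposed replicate 2 alone as the comparison.

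Among Wnt ligands, inhibitors and pathway genes, 14 of 25 measured genes had a log2 fold change above 0 and 11 below 0, and none passed. Over all tested probe sets 14200 of 25200 lay above 0, with a median of 0.04. Unnamed probe sets averaged -0.18 relative to named ones, from which all lists are drawn. A share above 0 or a small positive median of a list is therefore not by itself a rise of that list. Lgr5, a receptor for R-spondins that marks supporting cells, averaged 5.99 ± 0.28 (SD, n = 3) in noise-exposed and 6.54 ± 0.14 in unexposed mice (log2 fold change -0.54, adjusted p = 0.669). Axin1, a scaffold of the complex that degrades beta-catenin, had a log2 fold change of 0.54 and Dkk1, a secreted Wnt inhibitor, one of -0.48. Dkk1 lay at or below the cutoff on 1 of the 3 noise-exposed arrays. The camera test of this list pointed down (adjusted p = 0.684), while its median of 0.08 and mean of 0.03 were above 0.

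Across the receptors that the authors had selected by Gene Ontology terms, 473 of 1369 probe sets, of 296 genes, lay above the cutoff on all 6 arrays. The highest scores belonged to Prss12, a neuronal serine protease, Oprl1, the nociceptin receptor, Acvr2a, an activin receptor, Fzd9 and Fzd5. Prss12 averaged 7.19 ± 0.24 (SD, n = 3) in noise-exposed and 6.45 ± 0.25 in unexposed mice, and Oprl1 6.22 ± 0.28 against 5.54 ± 0.14. The lowest scores belonged to Stam2, an endosomal sorting adaptor, Slit2, a secreted axon repellent, Cd3e, Pcsk5 and Gabrb2, a GABA-A receptor subunit. Stam2 averaged 4.45 ± 0.16 against 5.15 ± 0.11, Slit2 7.65 ± 0.04 against 8.35 ± 0.32, and Gabrb2 4.77 ± 0.59 against 5.80 ± 0.37. No probe set passed in significance analysis of microarrays with a t-type score and all 20 label assignments (lowest q 0.306 among lower and 0.558 among higher probe sets). limma called 0 adjusted over the list alone (lowest adjusted p = 0.494) and 0 over all probe sets. At an unadjusted p under 0.05 there were 36 probe sets, 16 higher and 20 lower, where chance gives 23.65 in both directions together. The scores without a signal selection, or without any of 5 of the 6 arrays, called 1 to 3 probe sets. Each had a q of 0, which gives no error rate with so few arrays.

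The authors' deposited list, made with a rank statistic and a minimum fold change of 1.45, names 9 receptors as higher after noise at a q-value of 0%. They are Scara5, Prss12, Aplnr, Oprl1, Fzd5, Gpr37l1, Ror1, Fzd9 and Plxnb1, with deposited fold changes from 1.75 (Scara5) to 1.46 (Plxnb1). The deposited fold changes equal ratios of geometric means. The same 9 probe sets were the ones with every noise-exposed value above every unexposed value and a ratio past that minimum, by geometric means and by linear means. Another 12 probe sets by geometric means and 11 by linear means, among them Stam2, Slit2, Gabrb2 and Epha3, were separated in the opposite direction past the same minimum. Without the fold minimum 33 probe sets were separated upward and 33 downward, where chance gives 23.65 in each direction. The largest log2 fold change of the 9 in limma was 0.81 for Scara5 (SE 0.28, adjusted p = 0.685). The other tested probe set of Plxnb1, that of Epha3 and 1 of the other 3 of Gabrb2 had log2 fold changes of opposite sign.

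**Figure D2:**
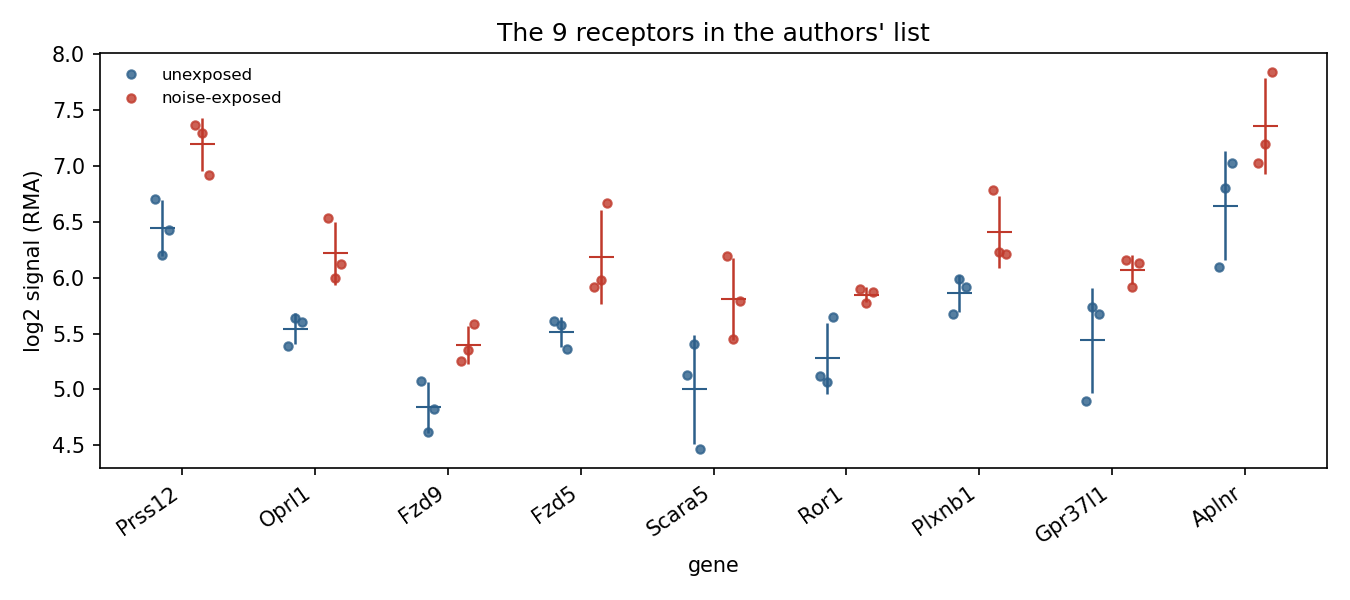
Log2 signal (y axis) of the 9 receptors in the authors' deposited list (x axis) in unexposed (blue) and noise-exposed (red) mice; points are single arrays, dashes are means and vertical lines are SD (n = 3). In each of the 9 the lowest noise-exposed value lies above the highest unexposed value, which was the selection itself, and adjusted over the 473 probe sets the lowest p was 0.494.

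Guidance and growth factor receptors outside the Wnt family also gave no call. Their counts above 0 stand beside 14200 of 25200 for all tested probe sets. That total includes unnamed probe sets, which averaged lower than the named ones in the lists, so it is a low yardstick. Among netrin, slit, semaphorin and hedgehog receptors, 11 of 19 measured genes had a log2 fold change above 0 (camera adjusted p = 0.875), led by Plxnb1, a semaphorin receptor, at 0.55 (SE 0.20) and Robo4 at 0.61 (SE 0.29). Robo4 lay at or below the cutoff on 1 of the 3 unexposed arrays. Among Eph receptors and ephrins 8 of 16 lay above 0 (adjusted p = 0.596), and Epha3 averaged 4.82 ± 0.14 (SD, n = 3) in noise-exposed against 5.65 ± 0.47 in unexposed mice. Among neurotrophic and growth factor receptors 22 of 29 lay above 0 with a median of 0.08 (adjusted p = 0.875), with Insr, the insulin receptor, at 0.42. Il6st, the shared subunit of interleukin-6 type receptors, was at 0.32 on its brighter probe set and at -0.39 on the other tested one. Myelin inhibitor and phosphatase receptors had 5 of 7 above 0, while camera pointed down (adjusted p = 0.913). For glutamate, GABA and acetylcholine receptors 13 of 21 genes lay below 0, with Grik2 at -0.46 on its brighter probe set and at 0.01 on another. Gabra5 was lower in noise-exposed mice, below the cutoff on all 3 of their arrays, and the kainate receptor gene Grik3 was higher, with an unexposed mean below the cutoff, so no exact size is given for either. That list had a camera adjusted p of 0.0877, and an adjusted p = 0.819 with an estimated correlation.

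Over the whole array no probe set passed the test. limma on 25200 probe sets gave 0 calls at an adjusted p under 0.05, with a lowest adjusted p of 0.265. At an unadjusted p under 0.05 there were 1041 higher and 740 lower probe sets, 1781 in all, where chance gives 1260. Significance analysis of microarrays over the same probe sets called 1, a probe set without a gene name here. Its q was 0, from a median false count over few assignments, which gives no error rate. The groups did not overlap for 3399 probe sets, 13.5% of those tested, where chance gives 10%. The median SE of a log2 fold change was 0.19, and 138 probe sets differed by 2-fold or more. In simulated data of this size, with 200 probe sets changed together, limma called 34% of those changed by 1 on the log2 scale. It called 85% of those changed by 2. An isolated change faces a stricter adjusted threshold, so these shares do not give its power. Without unexposed replicate 2 there were 15 calls, and with the first day alone 3 calls, with Xist among the calls in both.

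The genes with the lowest unadjusted p in each direction were given as values, since none was called. Higher in noise-exposed mice were Arg2, the mitochondrial arginase, with 5.90 ± 0.35 (SD, n = 3) against 4.65 ± 0.22 (log2 fold change 1.25, SE 0.21), Pip5kl1 at 1.17 and Rexo5 at 0.89. Sox2ot, Niban3 and Zfp862-ps lay between 0.73 and 0.77. Lower were Ttn, the giant muscle protein titin, with 3.97 ± 0.11 against 5.49 ± 0.23, Myocd, a coactivator of smooth muscle genes, at -1.32, Meis1 at -1.05, Acot4, Irf4, a transcription factor of lymphocytes, and Ubox5. Ttn, Acot4 and Irf4 lay below the cutoff of 4.25 on all 3 noise-exposed arrays, so their signal there is not above background and no exact size of the difference is given. The adjusted p of these 12 genes ranged from 0.265 for Ttn to 0.667. Other tested probe sets of Ubox5 and Meis1 had the opposite sign.

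Neuronal genes showed little difference as groups. Of 25 measured neuronal markers 16 had a log2 fold change above 0, with a median of 0.03, while camera pointed down (adjusted p = 0.875). Tubb3, the neuronal beta-tubulin, averaged 9.39 ± 0.12 (SD, n = 3) in noise-exposed and 8.92 ± 0.15 in unexposed mice (log2 fold change 0.48, SE 0.15, adjusted p = 0.667), and Nefm, a neurofilament, 10.91 ± 0.15 against 10.71 ± 0.15. Of 22 neuronal ion channel genes 12 lay below 0 (adjusted p = 0.209), with the potassium channel genes Kcnd2 at -0.77 and Kcna4 at -0.49 and the subunit Kcnab2 at 0.32. Of 17 genes of axon injury and regeneration 9 lay below 0 (adjusted p = 0.684), among them Smad1 at -0.32, while Jun was at 0.31.

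Markers of glia and other cell types were compared because the dissected tissue is a mixture. Central glia, which myelinate the central part of the auditory nerve, had 8 of 9 genes above 0 with a median of 0.35 (camera adjusted p = 0.209, and 0.819 with an estimated correlation between genes of 0.81). Without unexposed replicate 1 the median was 0.05 (adjusted p = 0.818), so 1 array carried most of this difference. Adjusted over the list alone 1 gene of it passed: Mobp, an oligodendrocyte myelin protein, had a log2 fold change of 0.78 (SE 0.19, adjusted p = 0.0333 over the list, 0.667 over all probe sets). This adjustment was made in each of 33 lists without correction for their number, and 2 of them held a passing gene. Mog, another oligodendrocyte gene, was at 0.51. Of 18 Schwann and satellite glial genes 11 lay above 0 (adjusted p = 0.684), with S100b at 0.32 and Mbp at 0.25. Osteoblasts and osteocytes had 10 of 12 above 0 with a median of 0.28 (adjusted p = 0.209), osteoclasts 3 of 4 (0.913), fibroblasts and matrix 13 of 17 (0.684, with Bgn at 0.51), and macrophages and microglia 15 of 17 (0.561, with Tyrobp, a signalling adaptor, at 0.50). Endothelial cells and pericytes had 10 of 15 above 0 (0.875), hair cells 3 of 5 (0.636), cochlear supporting cells 5 of 8 (0.684), spiral ligament and stria vascularis 8 of 13 (0.875) and erythroid cells 3 of 7 (0.688). All tested probe sets had 14200 of 25200 above 0, a low yardstick, since it includes unnamed ones, which averaged lower than named ones. For osteoclasts, endothelial cells and pericytes, hair cells and cochlear supporting cells camera pointed down, although most of their genes lay above 0. With the day of dissection in the model the median of the central glia list was 0.89, against unexposed replicate 1 alone, and with sex in the model it was -0.13, against unexposed replicate 2 alone.

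Some cell types gave too few measured genes for a test. The neutrophil lineage had S100a9 at 0.77 (SE 0.52), at or below the cutoff on 1 of the 3 unexposed arrays. S100a8 had a higher mean in noise-exposed mice and lay at or below the cutoff on 2 unexposed arrays, so no exact size is given. B cells had Cd74 at 0.29 and Ebf1 at -0.10, the 2 genes measured of 15. Skeletal muscle had Pvalb at 0.01, the only 1 measured of 14 and also in the neuronal marker list. Genes this few cannot stand for their cell types. T and NK cells had Cd3e, a subunit of the T-cell receptor complex, and Thy1, also a neuronal gene, at 0.03. Cd3e had a log2 fold change of -0.66 (SE 0.18), which passed adjusted over the list alone, of 2 genes (limma, adjusted p = 0.0123), and over all probe sets its adjusted p was 0.667. The adjustment over a list alone was made in 33 lists without correction for their number.

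**Figure D3:**
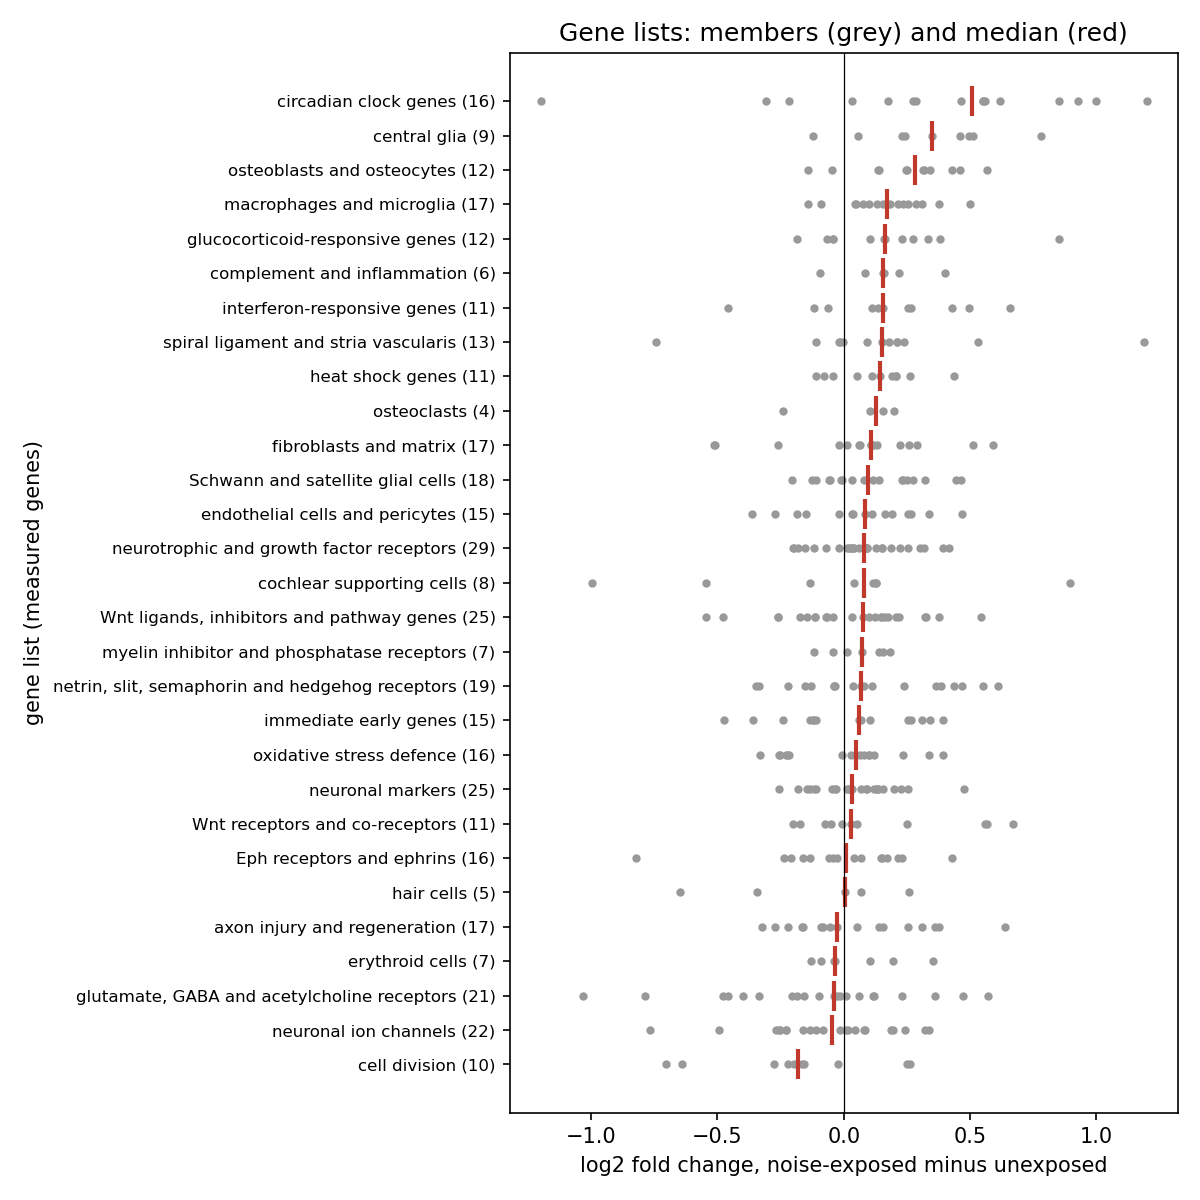
Log2 fold change, noise-exposed minus unexposed (x axis), of the measured genes (grey points) and their median (red bar) in each of 29 fixed gene lists (y axis, with the number of measured genes). Medians run from -0.18 for cell division to 0.51 for circadian clock genes, and 0 lists passed the camera test. The median over all tested probe sets was 0.04, with unnamed ones included, which averaged lower than named ones.

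Of the 29 lists with at least 3 measured genes, camera called 0 at an adjusted p under 0.05 (6 at an unadjusted p under 0.05), camera with an estimated correlation 0 (lowest adjusted p = 0.819) and fry 0 (lowest adjusted p = 0.136). Circadian clock genes had the highest median, 0.51, with 13 of 16 above 0 (camera adjusted p = 0.0877, and 0.819 with an estimated correlation). Without unexposed replicate 2 the median was 0.33 (adjusted p = 0.277), without unexposed replicate 3 it was 0.30 (adjusted p = 0.554), and without unexposed replicate 1, of the first day, 0.68 (adjusted p = 5.3e-05, and 0.511 with an estimated correlation). Dbp averaged 9.48 ± 0.37 (SD, n = 3) in noise-exposed and 8.49 ± 0.65 in unexposed mice, and Nr1d1, a repressor in the clock, 6.75 ± 0.31 against 5.83 ± 0.48. The arrays of the 2 days did not overlap for 12 of the 16 clock genes, where chance gives 13.3% and all tested genes gave 16.7%. Npas2, a partner of the core clock, lay between 5.61 and 6.19 on the first day and at 7.64 and 7.97 on the second, and Per2 between 7.06 and 8.18 against 5.20 and 5.69. With the day of dissection in the model, which compares with unexposed replicate 1 alone, the median of this list was 0.10 and the camera direction turned downward (adjusted p = 0.533). Cell division genes had 8 of 10 below 0 (adjusted p = 0.209). Stress and immune lists lay near 0 or slightly above: glucocorticoid-responsive genes with a median of 0.16 (0.688), heat shock genes 0.14 (0.688), immediate early genes 0.06 (0.688), oxidative stress defence 0.05 (0.636), interferon-responsive genes 0.15 (0.684) and complement and inflammation 0.16 (0.688). The median over all tested probe sets, with the lower unnamed ones included, was 0.04. Camera pointed down for immediate early genes and oxidative stress defence. Oasl2, of the interferon-responsive list, was higher in noise-exposed mice. It lay at or below the cutoff on 2 of the 3 unexposed arrays, so no exact size is given.

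**Figure D4:**
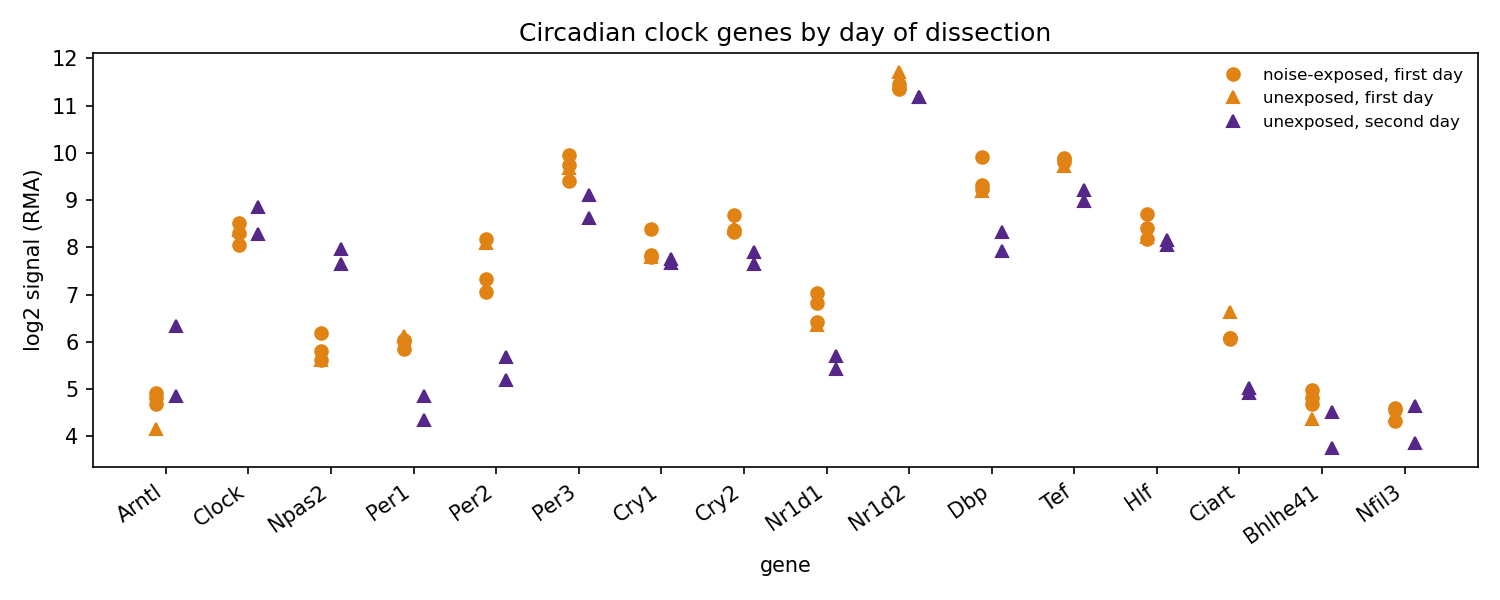
Log2 signal (y axis) of the 16 circadian clock genes (x axis) on single arrays; orange marks the 4 arrays of the first day of dissection and purple the 2 of the second, with circles for noise-exposed and triangles for unexposed mice. For 12 of the 16 genes the arrays of the 2 days do not overlap, and the unexposed array of the first day lies near the noise-exposed ones in Npas2 and Per2.

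Sex-linked genes matched the labelled sex of every mouse. Eif2s3y, a Y-linked gene, lay between 2.36 and 2.60 in the 4 females and at 9.56 and 9.70 in the 2 males on its brighter probe set, and Kdm5d between 2.30 and 3.08 against 7.39 and 8.17. Xist, the transcript that silences an X chromosome, lay at 8.75 to 9.09 in females on the probe set with the widest gap and at 2.75 and 4.47 in males. Uty, also Y-linked, lay between 2.39 and 2.81 in females and at 5.28 and 5.52 in males on 1 of its probe sets.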

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

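The alternatives were fixed before the data were examined, except the rank criterion, the restriction to probe sets with 1 gene symbol and the estimated correlation outside the main fit. The values were log2, so a constant added before log2 was not run. limma called 0 probe sets in the fits with another scaling, filter, covariate, replicate block or trend, with a 2-fold minimum, with females only, or with named probe sets alone. It called 3 with the first day alone, SAM called 1, and leaving out 1 array gave 0 to 15 calls, the 15 without unexposed replicate 2, the female. Both sets hold Xist and Orly. With only males unexposed, they cannot tell sex from noise. The SAM cause was not tested. Counts at an unadjusted p under 0.05 ran from 1106 (without noise-exposed replicate 1) to 3188 (females only). The fits with females only or the first day alone set 3 arrays against 1 and assume that the lone one varies like the others; with sex or day in the model the group difference is against the same lone array. Receptors detected ranged from 66 with the cutoff raised by 1 to 91 with it lowered by 1. SAM on the receptors called 1 without the signal selection (Htr2c) and 0 to 3 when 1 array was left out: 0 without noise-exposed replicate 3, and 3 without unexposed replicate 1 (Agtrap, Epha3 and Pcsk5). It called Neo1 without noise-exposed replicate 1, 2 probe sets of Gabrb2 without noise-exposed replicate 2, and Gpr61 without unexposed replicate 2. In the main fit the Neo1 probe set called there was at 0.79, and the other tested ones at 0.36, 0.25, -0.36 and -0.59. Without unexposed replicate 3 SAM called Ror1 and an unnamed probe set. Each of these SAM calls had a q of 0, from a median false count over few assignments, which gives no error rate. The rank criterion with the fold minimum gave 9 upward and 20 in both directions by linear means, and 9 and 21 by geometric means; it sets no error rate, and the cause was not tested otherwise. The number of gene lists called by camera at the preset correlation was 1 after centring on the median (transmitter receptors, down), 1 without a filter and 1 with the mean over probe sets (clock genes, up in both), 2 with females only (clock and glucocorticoid-responsive genes, up), 3 with RNA input (transmitter receptors and cell division down, central glia up), 3 with the day in the model and 3 with the first day alone (central glia up, glucocorticoid-responsive and cell division genes down). Leaving out 1 array gave 0 to 3 lists, 0 without replicate 3 of either group and 3 without unexposed replicate 1 or 2. With an estimated correlation it was 0 in the main fit and in every alternative, and with fry it was 0. The direction of a list turned in 86 of 522 values under an alternative; named here are lists with an unadjusted camera p under 0.05 in the main fit or a call in the alternative that turned it. It turned for central glia (median -0.13) and cell division (0.10) with sex in the model or females only. It turned for osteoblasts and osteocytes (-0.0013), glucocorticoid-responsive genes (-0.23) and clock genes (0.10) with the day in the model or the first day alone. The glucocorticoid list also turned, without a call, with sex and day together (-0.35), RNA input, or without noise-exposed replicate 3 or unexposed replicate 2 or 3. With sex and day together it turned for transmitter receptors (0.10), osteoblasts and osteocytes (-0.38), clock genes (-0.21), and for Scara5 (-0.27), Slit2 (0.042), Kcnd2 (0.53), Dbp (-0.12), Otog (-0.77) and Bhlhe41 (-0.30); the unexposed means of the last pair lie below the cutoff, so these values give no size or direction. The cause was not tested for these, apart from the clock genes. Of 2755 values of single genes under an alternative, 128 others changed sign, each from a value with an unadjusted p of 0.05 or more. Among them 1 gene, Pip5kl1, was called, without unexposed replicate 2, which left only males unexposed and cannot tell sex from noise. With the replicate block limma called 0 probe sets and camera 0 lists; the residuals of same-numbered arrays correlated at 0.094, 0.025 and -0.038, and 0 of 6 arrays correlated best with their own number, so the numbers do not pair the mice.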

Other observations

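The tests in this part were chosen after the results were seen. Values of glial and glucocorticoid-responsive genes were uneven between single mice within a group; this was not tested. The central glia list was lowest in unexposed replicate 1, with a mean deviation of -0.66 on the log2 scale, against 0.23 and -0.07 in the other unexposed mice and -0.07, 0.25 and 0.32 in the noise-exposed mice. Mobp lay at 9.52 in unexposed replicate 1 and at 10.00 and 10.08 in the others of its group, and at 10.47 to 10.74 in noise-exposed mice. Fkbp5, a cochaperone gene induced by glucocorticoids, lay at 7.91 in unexposed replicate 1, at 5.28 and 5.30 in the other unexposed mice and at 6.07, 6.40 and 7.16 in noise-exposed replicates 1, 2 and 3. Zbtb16, a transcription factor induced by the same hormones, lay at 8.98 in unexposed replicate 1 and 8.21 in noise-exposed replicate 3, and at 6.40 to 6.59 on the other arrays. Cell division genes had a mean deviation of 0.33 in unexposed replicate 1 and of -0.18 and 0.13 in the other unexposed mice.

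Male unexposed replicate 1 had more Xist than male unexposed replicate 3, at 4.47 against 2.75, 6.44 against 4.48 and 8.23 against 5.94 on the 3 probe sets. With sex as a covariate beside the group, the sex coefficient sets the 2 unexposed males against unexposed replicate 2, the only unexposed female. With day in its place, the coefficient sets the 2 second-day arrays against unexposed replicate 1 alone. Sex or day cannot be told apart there from a difference of that single mouse, so no count of calls is given. Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 1781 probe sets at an unadjusted p under 0.05, a count reached by 2 of 10 splits (highest other 1906, in the split that sets noise-exposed replicate 1 with both males). The real split gave 0 limma calls (highest other 0), 0 receptors in SAM (highest other 3) and 0 lists in camera (highest other 4); a count of 0 is reached by any split, so 10 of 10 was given in advance and these counts decide nothing.

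The day of dissection may account for the higher values of clock genes in the noise-exposed group, but it stays open. Among unexposed arrays alone, the root mean square log2 difference over the 16 genes between the first day and the second was 1.19, at percentile 99.4 of 10000 random lists matched on mean signal (median 0.35), but the first day has 1 unexposed mouse, so a difference of that mouse cannot be told apart from the day. The noise-exposed arrays differed from the unexposed array of their own day by 0.34, near the random median of 0.33, but a single array excludes nothing about noise. The amount of RNA also went with the day; noise-exposed replicate 3, with 10 ng, lay at 1.15 on a scale from the second-day arrays (0) to the other first-day arrays (1), where its RNA amount would place it at 0.28, again 1 array. The time of day of each dissection is not given in the sources used here, so a circadian difference stays a hypothesis.

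Probe sets without a gene name made up 15.2% of those tested, 43.5% of those lower and 7.40% of those higher at an unadjusted p under 0.05 (322 lower, 77 higher). Their median deviation relative to named probe sets was -0.10, -0.08 and -0.05 in the noise-exposed and 0.08, -0.01 and 0.15 in the unexposed arrays. Low signal as the whole cause is argued against in these 6 arrays, since after matching on mean signal they lay at -0.19 relative to named ones (95% interval -0.20 to -0.17), and at -0.15 among brighter probe sets. The interval comes from resampling probe sets with the arrays held fixed. It holds no spread between mice and gives no precision of the group difference. The yield of amplified cDNA stays open (Pearson's r = 0.56, exact permutation p = 0.251, adjusted 0.754, Spearman's rho = 0.54, exact p = 0.297, n = 6, 3 relations computed), and total RNA had r = -0.20 and biotinylated cDNA r = 0.10; without the 2 farthest arrays of each measure r was 0.75, -0.73 and -0.88 in this order, so single arrays set these values. Noise, sex and litter stay open too, since the exact two-sided permutation p of the group difference was 0.1, the smallest that 3 against 3 can give.

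By linear means the 9 receptors of the authors' list and the 11 separated in the opposite direction make 20 probe sets separated past the fold minimum, and by geometric means 21. Among the 10 splits 1, the real one, gave as many (highest other 18, and 19 by geometric means), and the splits are too few for a share under 0.05. In the upward direction alone, 6 of 20 assignments of the arrays gave 9 or more, with up to 14 in another assignment by linear means and 15 by geometric means, and a median of 4 by both. A difference between litters could give the same separation and cannot be told apart from noise, since 0 of the 4 litters held both groups.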
